A study of Mus musculus with 31 samples.

How the data were processed

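NIPBL and Rad21 ChIP-seq peak lists of 26 libraries were used, 1 list per library, so that replicates were never pooled. Per the submitters' processing notes, reads were aligned to mm9 with Bowtie2 and peaks were called with MACS2; the versions of both are not given in the sources used here. The lists are in the format that MACS2 writes for broad peaks. For each peak the authors deposited the fold enrichment over the peak caller's background (a ratio), the -log10 p-value and -log10 q-value, and a score that is 10 times the -log10 q. These belong to the peak in its own list and were used only to rank, filter or describe peaks within a list. Peak names inside the deposited lists give the control used for the Rad21 lists and for both NIPBL lists of CH12F3 replicate 2; the other NIPBL lists name none. All 3 i3CBEs lists share a control of their own and also hold peaks on 10 or 11 sequences outside the 21 main chromosomes, where the other lists hold 1. The 5 input samples were not analysed here. Groups and replicate numbers were taken from the sample titles. For the CH12F3 and i3CBEs Rad21 samples 1 label field names splenic B cells as the cell type, whereas the source name gives CH12F3 and the titles give CH12F3NCdel or i3CBEs, which were followed. Y chromosome peaks made up 0.00374% or less of the Rad21 lists of these samples, and in the splenic lists the group means lay between 0.0254% and 0.0355%. Stimulated splenic Rad21 replicate 2 stood apart, with 0.0103% on Y and the highest splenic share on X, 5.01%. The labels do not say whether replicates are separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

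Lists differed in length by over an order of magnitude and hold no read counts, so depth is unknown and coverage by peaks is the precision there is. From each list the 20000 peaks with the highest -log10 p on the main chromosomes were kept (ties by fold enrichment, then position). The genome was divided into 264200 bins of 10 kb, and the value of a bin in a library is the percent of its bases covered by these peaks. Bins covered in 2 or more libraries of a fit were tested with limma 3.58.1 (R 4.3.3, mean-variance trend), and the Benjamini-Hochberg adjusted p had to be under 0.05. Stimulated and unstimulated cells were compared within each antibody and cell type, each with its own fit; CH12F3 and i3CBEs Rad21 libraries shared a fit. An interaction term compared the effect of stimulation between spleen and CH12F3. The tests, the number of top peaks, the samples of each fit, the alternatives and the rule for named bins were chosen before the data were examined. By that rule the text may name, per comparison and direction, the 10 called bins with the largest difference whose groups do not overlap, or the 5 with the smallest p where none was called, and all bins of the IgH region. Bins were the fallback written down for the case that no mm9 annotation was at hand: promoters, gene lists, the promoter share of peaks and CTCF motifs, which were planned, were not analysed here. Bins discussed for both antibodies, for the interaction, for the X chromosome and for chromosome 16 were chosen after their values were seen. No list of regions prone to artefacts was used, so bins almost wholly covered by peaks were kept.

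In the IgH region, the mean covered percent of each bin was compared by two-sided exact permutation tests, adjusted over the covered bins of the region. The smallest p possible is 0.1 for 3 against 3 libraries, 0.33 for 2 against 2 and 0.057 for 3 against 4. Peak sets were compared with bedtools 2.31.1 by overlap of 1 or more bases, beside peaks moved by 1 Mb, and list sizes and shares of peaks per chromosome by the same exact tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used, with matplotlib 3.10.9 for figures. The number of bins expected under both antibodies is the product of both counts over the bins in the genome, and for bins called in both comparisons the product over the bins tested in both.

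The bin test was tested on simulated data. The values of each bin were shuffled between the libraries of a fit, then 100 bins were changed by 10 points and 100 by 20. This shuffle moves real group differences into the spread within groups, so recovery may differ from that in the real data. The test recovered 34 and 73 of the changed bins for NIPBL in spleen, 0 and 0 for NIPBL in CH12F3, 0 and 0 for Rad21 in spleen, 84 and 97 for Rad21 in CH12F3, and 72 and 99 for i3CBEs. With these changes present it also called 80, 0, 0, 14 and 12 unchanged bins. For NIPBL in spleen the 80 stood beside 34 and 73 recovered bins, so that its adjusted p-values were too small in these simulated data. The 14 for Rad21 in CH12F3 and the 12 for i3CBEs do not decide this, because the adjustment allows a small share of false calls. Without any change it called 6 bins for NIPBL in spleen and 0 in the other comparisons. As a second check, the values of each bin were shuffled between libraries 20 times. The p of the last called bin was then passed by a mean of 100.4 bins against 548 calls for NIPBL in spleen, 50.9 against 637 for Rad21 in spleen and 8.45 against 94 for i3CBEs. Such a shuffle can restore the real division of a called bin, so these means also count real differences, as the 80 unchanged bins above may.

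Where both groups of a comparison share replicate numbers, the correlation of same-numbered libraries' deviations from their group means over the tested bins was computed before the fits were compared. It was 0.417, 0.642 and 0.371 for Rad21 in CH12F3, so these were treated as paired and the fit with the replicate number as a block, without the unmatched stimulated replicate 4, is given beside the result. Libraries with different numbers also deviated together (stimulated 1 with unstimulated 3 at 0.437, 3 with 1 at 0.352 and 4 with 2 at 0.585), so the pattern is one of replicates 1 and 3 against 2 and 4; the labels do not say what a number stands for. Alternatives were 10000 and 40000 top peaks, an equal covered length of 10 Mb, all deposited peaks, peaks with a -log10 q of 5 or more, ranking by fold enrichment, bins scored by whether 50% was covered, no filter on bins, array weights, all groups of an antibody in 1 fit, the replicate block and each replicate left out. Bins of 5 kb, bins scored as covered or not, a term for list length and a fit without X and Y were added after the data had been seen.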

Results

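Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map NIPBL, the protein that loads the cohesin complex onto DNA, and Rad21, a subunit of cohesin itself, in mouse B cells that lack AID, the enzyme that starts class switch recombination. According to its design text, the study asked what part loop extrusion by cohesin plays in class switching at the immunoglobulin heavy chain (IgH) locus. Of 31 samples, 26 came with a peak list and 5 were input samples, which were not analysed here. The 10 NIPBL libraries came from mature splenic B cells without stimulation (n = 3) or after 48 h of anti-CD40 and IL-4 (n = 3), and from CH12F3, a mouse B lymphoma line, without stimulation (n = 2) or after 24 h of anti-CD40, IL-4 and TGF-β (n = 2). Sample titles name the line CH12F3NCdel, which the labels do not expand; it is written CH12F3 here. The 16 Rad21 libraries came from unstimulated (n = 3) and stimulated (n = 3) splenic B cells, unstimulated (n = 3) and stimulated (n = 4) CH12F3 cells, and stimulated cells named i3CBEs (n = 3), whose source the labels give as CH12F3. The labels do not expand that name.

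Read depth is unknown, because the lists hold peaks and no read counts; the number of peaks and the length they covered were used to describe each list. NIPBL lists held 890499 to 1332862 peaks. Rad21 lists held 95464 to 271662 peaks in CH12F3 and 97738, 53237 and 42659 in i3CBEs. Splenic Rad21 lists were uneven: the unstimulated replicates held 292078, 1177389 and 152152 peaks and the stimulated replicates 149409, 1166191 and 1236385. In proportion, the largest gap in covered length between compared groups was in i3CBEs, whose peaks covered 11.7 ± 2.20 Mb (SD, n = 3) against 32.5 ± 12.2 Mb in stimulated CH12F3 (n = 4). Its two-sided exact permutation p was 0.057, the smallest that 3 against 4 libraries allow, and the adjusted p over 25 tests of list size and width was 0.476. As chosen before the data were examined, every library was reduced to its 20000 strongest peaks before it was compared, so that lists of unequal length could be compared. Of the i3CBEs libraries, the 20000 peaks were narrower, with a median width of 257 ± 21.9 bp against 378 ± 67.1 bp in stimulated CH12F3 (exact permutation p = 0.057, adjusted p = 0.476, two-sided).

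Rad21 sites were shared widely between libraries, and NIPBL sites much less. In CH12F3, 87.4 ± 2.51% of a library's top Rad21 peaks overlapped a top peak of another replicate by at least 1 base (SD over 18 ordered pairs of libraries), and 88.0 ± 2.13% did so between stimulated and unstimulated cells (24 pairs). Rad21 peaks of i3CBEs overlapped those of stimulated CH12F3 at 83.5 ± 1.34% (24 pairs), and those of spleen and CH12F3 overlapped at 69.4 ± 5.29% (84 pairs). Splenic Rad21 replicates shared 77.9 ± 4.43% of peaks within a group and 69.4 ± 4.55% between stimulated and unstimulated cells. NIPBL replicates shared 47.6 ± 2.41% within a splenic group, 44.0 ± 3.98% between splenic groups and 17.6 ± 3.37% within a CH12F3 group. This last value lay below the 25.5 ± 11.2% shared between splenic and CH12F3 NIPBL libraries (48 pairs); of the CH12F3 NIPBL lists, those of replicate 2 name a control and those of replicate 1 do not, and whether both were called alike is not given in the sources used here. NIPBL and Rad21 libraries of the same cells shared 10.7 ± 3.22% of peaks in spleen and 6.50 ± 3.18% in CH12F3. Peaks moved by 1 Mb overlapped at 0.788% to 1.63% on average. Pairs share libraries, so these SDs describe spread and no test was run. No library was a copy of another, since at most 1.11% of peaks had the same start in any pair. With all deposited peaks in place of the strongest, CH12F3 Rad21 replicates shared 43.7%, splenic Rad21 replicates 26.2% and splenic NIPBL replicates 25.7%, while CH12F3 NIPBL replicates shared 29.8%.

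**Figure D1:**
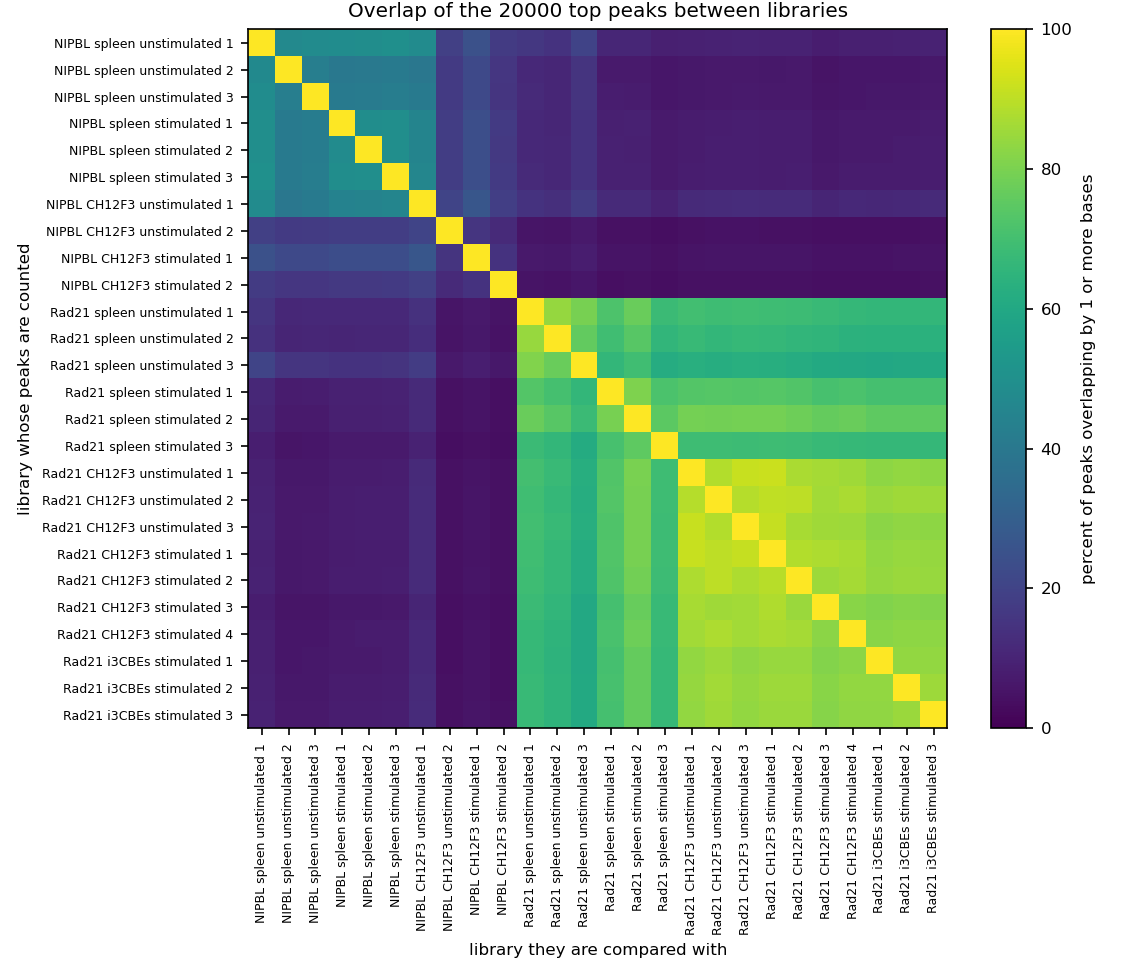
Percent of each library's 20000 top peaks (vertical axis) that overlap a top peak of every other library (horizontal axis) by 1 or more bases, on a colour scale from 0 to 100. Rad21 libraries share most of their peaks with each other, with pairs of up to 91.8%, whereas NIPBL and Rad21 libraries of spleen share 10.7% on average.

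In splenic B cells, the effect of stimulation on NIPBL was asked for bins of 10 kb (coordinates in mm9), as percent of the bin covered by top peaks. Of 18332 bins, 321 gained coverage and 227 lost it (limma, adjusted p under 0.05). The strongest gain lay on chromosome 7 from 52090001 to 52100000, where coverage was 93.7 ± 5.49% in stimulated and 25.9 ± 4.87% in unstimulated cells (SD, n = 3 each; adjusted p = 0.00424). The bin at 90150001 on chromosome 1 followed with 61.8 ± 1.89% against 5.13 ± 8.89% (adjusted p = 0.00845). Next came the bin at 2790001 on the Y chromosome with 49.1 ± 11.1% against 6.33 ± 5.02% (adjusted p = 0.021; -1.31 points with 10000 top peaks), and the bin at 114570001 on chromosome 12, inside the IgH region, with 38.7 ± 12.9% against 0 in all 3 unstimulated libraries. Other gains from 0 were seen at 75930001 on chromosome 15 (35.4 ± 0.907%; -4.39 points for peaks with a -log10 q of 5 or more), at 53070001 on chromosome 13 (30.7 ± 2.57%) and at 91730001 on chromosome 15 (29.7 ± 0.0954%). Among the losses, coverage was 2.36 ± 4.09% after stimulation and 47.6 ± 8.03% before it at 101080001 on chromosome 15, 7.85 ± 4.12% and 49.1 ± 2.72% at 121940001 on chromosome 8, and 8.66 ± 0.746% and 46.8 ± 0.318% at 15180001 on chromosome 14. The X chromosome held 29 of the 227 losses against 4.59 expected from its share of tested bins, with coverage at 70960001 of 0 after and 26.9 ± 5.96% before stimulation. Each of the 548 called bins had groups that did not overlap. Their median difference was 10.6 percentage points for gains and 10.1 for losses, and 262 of the gains started from 0 in every unstimulated library.

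When values of this comparison were shuffled within bins 20 times, a mean of 100.4 bins passed the p of the last called bin, or 18.3% of the 548 calls. A shuffle can restore the real division of a called bin, so this share also counts real differences. It is therefore no clean estimate of false calls. The adjusted p-values may still be too small, as 80 unchanged bins were called in the data simulated for this comparison. That simulation also shuffled real values, so the 80 can hold restored real differences, and without added changes it called 6 bins. The balance between gains and losses depended on how lists were scaled, with 380 gains and 458 losses for 10000 top peaks, 331 and 66 for 40000, 517 and 454 for lists of equal covered length, and 1442 and 89 for all deposited peaks. For peaks with a -log10 q of 5 or more limma called 0 bins (676 higher and 12866 lower with an unadjusted p under 0.05). With all NIPBL groups in 1 fit it called 174 gains and 126 losses. Single libraries moved the counts by over 1.5 times: gains numbered 655 without unstimulated replicate 1 and 652, 540 and 521 without stimulated replicates 1, 2 and 3, and losses 362, 349 and 371 without unstimulated replicates 1, 2 and 3.

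The IgH region was taken as the 40 bins of chromosome 12 from 114300001 to 114700000, where the locus lies in mm9. A RefSeq gene table of another assembly, GRCm38.p6, lists the constant-region genes by ascending coordinate as Igha, Ighe, Ighg2c, Ighg2b, Ighg1, Ighg3, Ighd and Ighm; which of the mm9 bins hold which gene was not worked out here. Anti-CD40 with IL-4 is known to direct splenic B cells towards IgG1 and IgE, and the cytokines given to CH12F3 direct that line towards IgA. In stimulated splenic B cells, NIPBL formed a broad peak in each of the 3 libraries in the bin at 114570001: from 114572412 to 114576583, from 114573079 to 114577984 and from 114572735 to 114575180, with fold enrichments of 9.13, 8.39 and 11.3 in the authors' lists. No unstimulated library had a top peak in this bin, and limma gave a difference of 38.7 points (SE 6.27, adjusted p = 0.0358). With all deposited peaks the bin was covered at 64.4 ± 5.43% after and 18.8 ± 7.83% before stimulation. The neighbouring bin at 114560001 was covered at 13.9 ± 7.49% against 0, and the bin at 114470001 at 11.1 ± 2.17% against 0 (adjusted p = 0.0172). With all deposited peaks the latter bin was covered at 44.12 ± 8.71% after and 42.65 ± 8.62% before stimulation, so its gain holds for top peaks only. NIPBL coverage was lost in the bin at 114400001, from 13.0 ± 3.21% to 0 in all 3 stimulated libraries (adjusted p = 0.0239). With all deposited peaks the difference at 114400001 was 12.1 points, and for peaks with a -log10 q of 5 or more that at 114470001 was -2.79 points; over the alternatives their adjusted p ranged from 0.00431 to 0.617 and from 0.00298 to 0.952. The bin at 114660001 was covered in both states, at 40.6 ± 9.39% and 42.1 ± 12.5%. Of 22 covered bins, 8 were higher and 2 lower after stimulation without overlap of the groups. Chance gives at most 10%, and less in bins where libraries of both groups tie at 0. With 10000 top peaks 3 bins had groups without overlap, and with all deposited peaks 17. For each of these 10 bins the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, and the adjusted p over the 22 bins was 0.22. The gain at 114570001 kept its sign under every alternative run, at 33.1 to 48.5 points, but limma's adjusted p ranged from 1.29e-08 to 0.183 and was between 0.0518 and 0.124 without stimulated replicate 1 or 2 or any one of the unstimulated replicates.

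**Figure D2:**
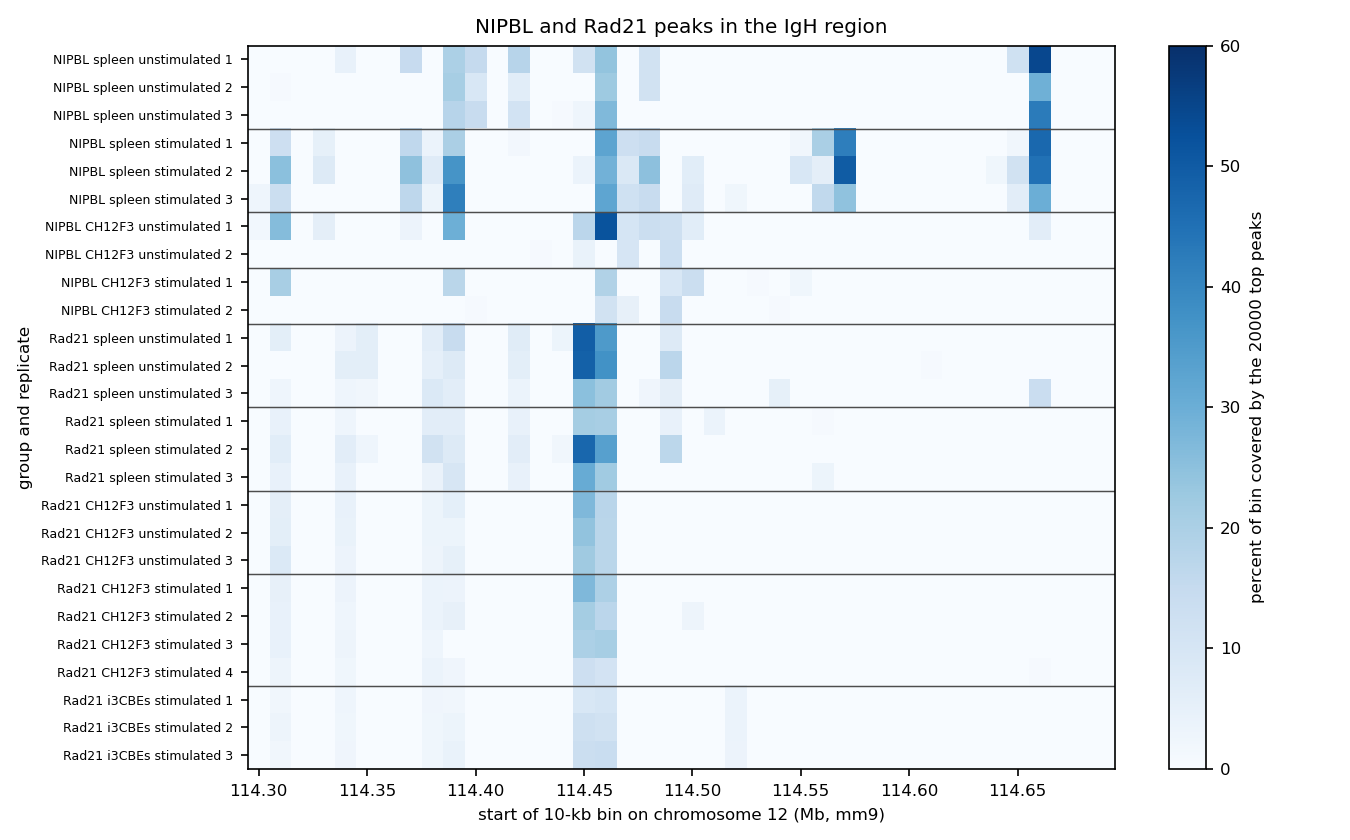
Percent of each 10-kb bin covered by the 20000 top peaks (colour, 0 to 60) along the IgH region of chromosome 12 (horizontal axis, start of bin in Mb, mm9), with 1 line per library. Top NIPBL peaks cover the bin at 114570001 in the 3 stimulated splenic libraries alone, and top Rad21 peaks cover the bins at 114450001 and 114460001 in all 16 libraries. Weaker peaks, which are not shown, also cover the bin at 114570001 in other libraries.

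Stimulation of CH12F3 was compared in the same way for NIPBL, with 2 libraries per group. No bin of 12315 passed limma's adjusted p of 0.05 in either direction, and 511 bins higher and 777 lower had an unadjusted p under 0.05. With lists of equal covered length these were 1908 and 587, again with no call, and with all NIPBL groups in 1 fit limma called 70 bins higher and 186 lower. With bins scored as covered or not, a setting added later, limma called 860 higher and 1429 lower. As many had an unadjusted p under 0.05, so the adjustment removed none. With such scores, a bin covered in both libraries of 1 group and in neither of the other has no spread within groups. Its p is then small by construction. Of bins covered in exactly 2 of the 4 libraries, chance divides 33.3% in this way, so these counts are no evidence of an effect of stimulation. In the main fit the smallest adjusted p was 0.353, shared by the bins with the smallest p. Among these, coverage at 13:55570001 was 0 in both stimulated libraries and 29.0 ± 5.17% in the unstimulated ones (SD, n = 2), and at 3:65330001 it was 0 against 21.9 ± 1.10%. The top peaks of the stimulated libraries were narrow, with a median width of 59.5 ± 12.0 bp against 396.5 ± 378 bp in the unstimulated ones, which limits what their coverage can show. In the IgH region, the bin at 114570001 had no top NIPBL peak in any of the 4 CH12F3 libraries. With all deposited peaks it was covered at 13.7 ± 2.28% after and 15.1 ± 9.9% before stimulation. The bin at 114470001 was covered at 2.45 ± 3.46% after stimulation and at 10.0 ± 0.0919% before it, and the bin at 114450001 at 0 against 10.6 ± 9.09%. These were the 2 bins of 17 whose groups did not overlap, where chance gives at most 33.3% and less in bins with ties at 0. The two-sided exact permutation p of 0.33 is the smallest that 2 against 2 libraries allow. In data simulated for this comparison, none of 100 bins changed by 10 points and none of 100 changed by 20 points was recovered.

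For Rad21 in splenic B cells, 608 of 22603 bins were lower after stimulation and 29 higher (limma, adjusted p under 0.05), a balance that depended on how lists were scaled. Coverage at 96080001 on chromosome 10 was 10.6 ± 12.7% in stimulated and 92.8 ± 3.59% in unstimulated cells (SD, n = 3 each; adjusted p = 0.0302). At 87560001 on chromosome 11 it was 1.37 ± 2.37% against 61.8 ± 13.5%, at 34430001 on chromosome 17 it was 6.19 ± 1.78% against 62.3 ± 8.97%, and at 5800001 on the same chromosome 0 against 53.1 ± 12.3%. Losses ran over neighbouring bins in 50 places, and the longest stretch was 6 bins on chromosome 11 from 87230001 to 87290000. On chromosome 9, 3 neighbouring bins were lost from 44370001 to 44400000 (1.07 ± 1.85% against 55.1 ± 14.5% in the first). On chromosome 2 a pair was lost at 58000001 and 58010001 (0 against 48.4 ± 18.0% in the former). The strongest gain was at 3070001 on chromosome 11, with 86.4 ± 7.06% against 2.99 ± 5.17% (adjusted p = 0.0302), but with all deposited peaks its difference was -1.54 points; the bin at 83190001 on chromosome 13 rose from 0 to 23.7 ± 6.23%. In the IgH region the bins at 114450001 and 114460001 were covered in all 6 libraries. The former held 33.0 ± 13.2% after and 41.0 ± 13.7% before stimulation (two-sided exact permutation p = 0.5) and the latter 25.4 ± 7.23% and 31.5 ± 8.53% (p = 0.3), with an adjusted p of 1 for both over 16 covered bins. None of these 16 bins had groups without overlap. With all deposited peaks, whose lists were uneven in length, Rad21 covered 114570001 at 36.8 ± 11.8% after and 0.68 ± 1.18% before stimulation, without overlap. Groups were also apart at 114560001 (43.1 ± 29.7% against 1.24 ± 2.14%) and 114510001 (22.5 ± 16.4% against 0.68 ± 1.18%). In that setting no IgH bin was lower without overlap.

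At an unadjusted p under 0.05, 1387 bins were higher and 2670 lower for the 20000 top peaks, which covered 10.6 Mb after and 13.2 Mb before stimulation, but 1681 and 987 for lists of equal covered length and 859 and 107 for all deposited peaks. These splenic Rad21 calls rest on the choice of peaks and on single libraries: limma called 0 bins in either direction with 10000 top peaks, with 40000, with lists of equal covered length, or without any one of the 3 stimulated replicates, where 2143 to 5369 bins had an unadjusted p under 0.05. In the groups as labelled, list length was uneven, and a term for lists of over 1000000 peaks also left 0 calls, with 1022 bins higher and 2750 lower at an unadjusted p under 0.05. Without unstimulated replicate 3, 1759 bins were lower, and without unstimulated replicate 1, 289. Array weights gave 1040 bins higher and 2896 lower, and all Rad21 groups in 1 fit 1122 and 2738. Values shuffled within bins passed the p of the last called bin in 7.98% as many bins as were called, a share that can include real differences. In data simulated for this comparison none of 100 bins changed by 10 points and none of 100 changed by 20 points was recovered. The simulation shuffles real group differences into the spread, so it does not show what this fit can detect. The bins called in the real data had a median difference of 14.0 points for losses and 7.58 for gains.

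Few bins changed for Rad21 when CH12F3 was stimulated. Of 22898 bins, 6 were lower and 0 higher (limma, adjusted p under 0.05), with 1001 lower and 361 higher at an unadjusted p under 0.05. The 6 bins held small peaks: 9:56770001 was covered at 0.480 ± 0.960% (SD, n = 4) against 6.91 ± 1.30% (n = 3), 7:29570001 at 0.590 ± 1.18% against 6.74 ± 0.835%, and 12:113850001 at 0 against 4.96 ± 0.912%. Bins 9:77600001, 16:36990001 and 14:27410001 fell by 4.57, 4.07 and 3.48 percentage points, with adjusted p-values of 0.0264 each, though 9:77600001 differed by 0.134 points with 40000 top peaks. The smallest adjusted p of a higher bin was 0.0707, at 1:80750001, which was covered at 5.24 ± 0.403% against 0; its difference was -2.84 points with 40000 top peaks, -2.95 with all deposited peaks and -1.25 for peaks with a -log10 q of 5 or more. Same-numbered CH12F3 libraries deviated together, as did replicates 1 and 3 across states. With the replicate number as a block, which also leaves out the unmatched stimulated replicate 4, limma called 0 bins in either direction, with 756 higher and 781 lower at an unadjusted p under 0.05. Without that replicate and with no block, 1 bin was higher and 3 lower, with 745 and 777 at an unadjusted p under 0.05. Adjusted p-values of the 6 bins then lay between 0.218 and 0.376. Without unstimulated replicate 2, 177 bins were lower and 18 higher, and without unstimulated or stimulated replicate 3 none was lower. In the IgH region, the bins at 114450001 and 114460001 were covered at 20.2 ± 5.82% and 17.1 ± 4.40% after stimulation and at 24.5 ± 2.45% and 17.3 ± 0.163% before it (two-sided exact permutation p = 0.343 and 0.971). Coverage at 114310001 and 114340001 was lower without overlap, at 4.16 ± 0.893% against 6.67 ± 1.41% and 2.85 ± 0.463% against 4.04 ± 0.53%, each with the smallest exact p possible, 0.057, and an adjusted p of 0.229 over 8 bins; with 10000 top peaks or all deposited peaks, 0 IgH bins had groups without overlap. Chance gives at most 5.71% of bins without overlap. In data simulated for this comparison, 84 of 100 bins changed by 10 points and 97 of 100 changed by 20 points were recovered. These data were shuffled and fitted without the block, so they do not hold the pattern of replicates 1 and 3 against 2 and 4.

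Stimulated i3CBEs cells were compared with stimulated CH12F3 to ask how Rad21 differs between them. Of 22898 bins, 41 were higher and 53 lower in i3CBEs (limma, adjusted p under 0.05). Neighbouring parts of chromosome 1 stood out among the lower bins, with coverage of 13.0 ± 8.77% in i3CBEs (SD, n = 3) and 98.3 ± 2.17% in CH12F3 (n = 4) at 85240001, 7.51 ± 13.0% and 86.9 ± 5.47% at 87490001, and 21.6 ± 16.2% and 82.7 ± 14.2% at 85100001. Chromosome 16 held 15 of the 53 lower bins, where 1.99 were expected, such as 45140001 with 2.08 ± 0.125% against 14.3 ± 2.14%. Among the higher bins, coverage was 28.9 ± 6.31% against 1.94 ± 3.88% at 15050001 on chromosome 5, and on the X chromosome it was 22.8 ± 1.76% against 0 at 31970001 (adjusted p = 8.21e-06) and 17.1 ± 6.31% against 0.638 ± 1.27% at 30480001. The X chromosome held 10 of the 41 higher bins, where 1.16 were expected from independent bins. Most of these 10 lay close together, in bins from 30480001 to 32190001. The X chromosome also held 3.40 ± 0.571% of the top peaks in i3CBEs against 2.23 ± 0.178% in stimulated CH12F3, without overlap (two-sided exact permutation p = 0.057, adjusted p = 0.4 over 21 chromosomes). Of all deposited peaks it held 4.27 ± 1.07% and 2.44 ± 0.578%, with overlap (exact p = 0.114, adjusted p = 0.48).

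Within the IgH region, i3CBEs had a Rad21 peak of its own in the bin at 114520001: from 114525504 to 114525868, from 114525505 to 114525876 and from 114525499 to 114525840 in the 3 replicates, with fold enrichments of 10.0, 8.62 and 8.38 in the authors' lists. The bin was covered at 3.60 ± 0.157% in i3CBEs and at 0 in all 7 CH12F3 Rad21 libraries (limma, adjusted p = 0.00791; 8.58e-05 to 0.13 over the alternatives, highest with all deposited peaks). Coverage at 114450001 and 114460001 was 11.7 ± 2.18% and 11.9 ± 1.87% in i3CBEs against 20.2 ± 5.82% and 17.1 ± 4.40% in stimulated CH12F3, with two-sided exact permutation p-values of 0.114 and 0.171. Of 9 covered bins, 1 was higher and 1 lower in i3CBEs without overlap, where chance gives at most 5.71%, and their adjusted p was 0.257. Across all tested bins the median difference was -1.22 percentage points, and the balance of calls moved with the scaling to 1694 higher and 200 lower for lists of equal covered length, 11 and 406 for peaks with a -log10 q of 5 or more, and 0 and 56 for all deposited peaks. Without 1 of the 7 libraries in turn, 3 to 72 bins were higher and 2 to 211 lower; the fewest higher were left without CH12F3 replicate 1 and the fewest lower without i3CBEs replicate 2.

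**Figure D3:**
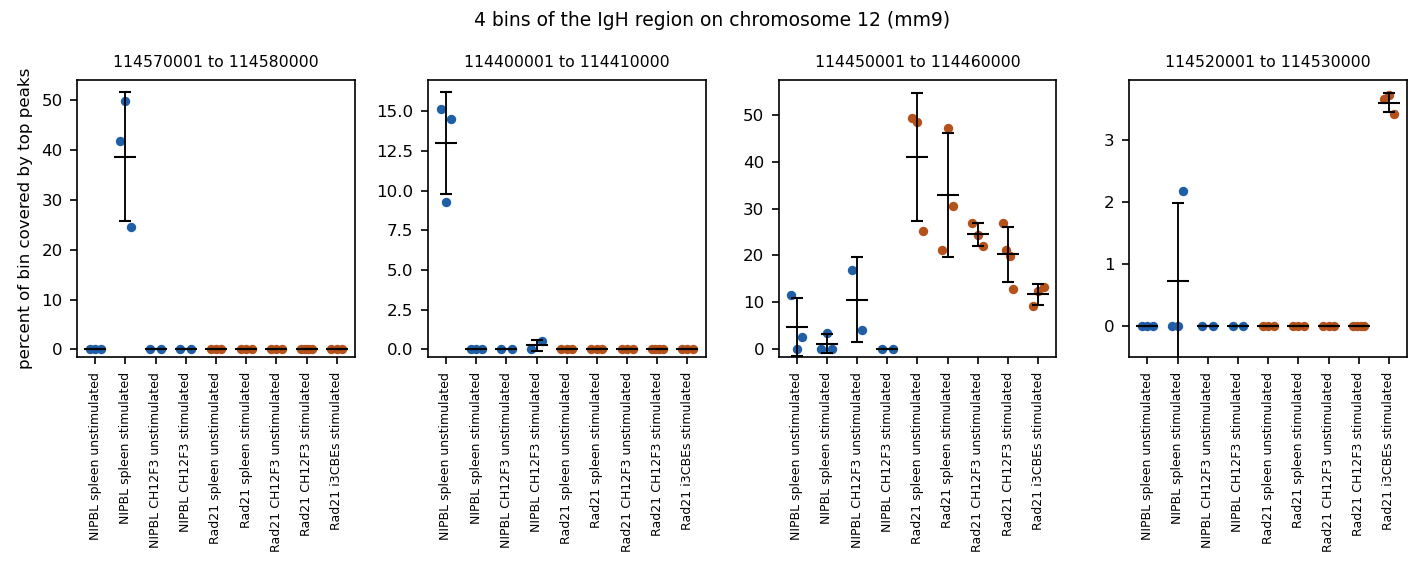
Percent of the bin covered by top peaks (vertical axis, a different scale in each panel) for 4 bins of the IgH region in the 9 groups; points are libraries (NIPBL blue, Rad21 orange), horizontal lines are means and bars are 1 SD. The bin at 114570001 is covered at 38.7% in stimulated splenic NIPBL libraries and the bin at 114520001 at 3.60% in i3CBEs Rad21 libraries.

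Whether stimulation acted differently in spleen and CH12F3 was tested by an interaction term in limma. For NIPBL, 3 of 30857 bins differed: at 77390001 on chromosome 9 the effect was 37.6 percentage points higher in spleen (SE 2.26, adjusted p = 0.00536), at 91730001 on chromosome 15 it was 29.7 higher (SE 2.17, adjusted p = 0.00816) and at 15180001 on chromosome 14 the difference was -38.2 (SE 2.68, adjusted p = 0.00816). At 91730001 and 15180001 these differences equal the effects in spleen, so mean coverage in CH12F3 did not change there. At 77390001, coverage in CH12F3 was 0 after and 20.8 ± 0.58% before stimulation (n = 2 each), a loss that reversed with all deposited peaks. At the IgH bins, the effect on NIPBL was 38.7 points higher in spleen at 114570001 (SE 8.67, adjusted p = 0.144) and 18.7 higher at 114470001 (SE 2.91, adjusted p = 0.0535), so neither difference between the cell types passed. For Rad21, 1277 of 27721 bins differed, 1083 of them with a more negative effect in spleen and 194 with a more positive one. The smallest p was at 43860001 on chromosome 13, where the difference was -41.7 points (SE 2.31, adjusted p = 3.7e-06), followed by 58320001 on chromosome 3 with -34.0 points (SE 1.94). Without CH12F3 stimulated replicate 4, limma called 1028 bins for Rad21, and 490 when the replicate number was also a block within each cell type. With 10000 top peaks, 514 bins differed for NIPBL and 353 for Rad21. The smallest adjusted p for Rad21 at an IgH bin was 0.252, at 114350001. Stimulation itself differed between the cell types, with TGF-β and 24 h in CH12F3 alone. Counts for the effect of stimulation on NIPBL rested on single libraries, with 3394 bins differing without NIPBL CH12F3 unstimulated replicate 2, and for all deposited peaks limma called 0 bins for NIPBL (20598 with an unadjusted p under 0.05) and 1 for Rad21.

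NIPBL and Rad21 met in the same bins more often than independent placement gives. In unstimulated splenic B cells, 4043 bins were covered by both against 832.8 expected, which was 33.6% of the NIPBL bins and 4.85 times the expected number. After stimulation 3071 bins were shared (833.6 expected, 3.68 times), and in CH12F3 1544 (4.11 times) without and 1020 (3.61 times) with stimulation. Both antibodies lost coverage in 28 bins of stimulated splenic B cells, among 6046 bins tested for both, where 7.96 were expected from independent lists. The strongest of these were 8:121940001, with -41.2 percentage points for NIPBL (SE 2.61) and -19.6 for Rad21 (SE 3.91), 9:44380001, with -6.72 and -51.2, and 2:118370001, with -27.4 and -14.8. NIPBL gains coincided with Rad21 losses in 1 bin, where 5.78 were expected. Of 128 bins that lost NIPBL, 89.8% had lower mean Rad21 coverage against 68.1% of all 6046, and of 93 that gained NIPBL, 49 had higher mean Rad21 coverage, or 52.7% against 31.9%. Across bins, which are not independent replicates, the differences of both antibodies were correlated with Pearson's r of 0.406 and Spearman's rho of 0.400. Neither the counts nor the correlation carry a p-value, and the splenic Rad21 calls have the limits given with them.

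The share of all peaks on single chromosomes also differed between some groups. NIPBL lists of stimulated splenic B cells had 3.10 ± 0.200% of their peaks on the X chromosome against 4.02 ± 0.0373% in unstimulated cells (n = 3 each; two-sided exact permutation p = 0.1, adjusted p = 0.131 over 21 chromosomes), and the Rad21 lists of the same cell types had 3.83 ± 1.20% and 3.70 ± 0.738% (exact p = 0.9), the former with 5.01% in replicate 2 and 2.61% and 3.85% in replicates 1 and 3. Chromosome 16 held 3.08 ± 0.190% of Rad21 peaks in i3CBEs (n = 3) and 6.44 ± 0.585% in stimulated CH12F3 (n = 4; exact p = 0.057, adjusted p = 0.48). None of these shares passed 0.05 after adjustment. For splenic NIPBL, an adjusted p so near the exact p of 0.1 arises only if most of the 21 chromosomes had shares without overlap. Chromosome 16 was 1 of them, with 3.607, 3.629 and 3.706% after and 3.831, 3.825 and 3.795% before stimulation. X was therefore not alone in this.

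**Figure D4:**
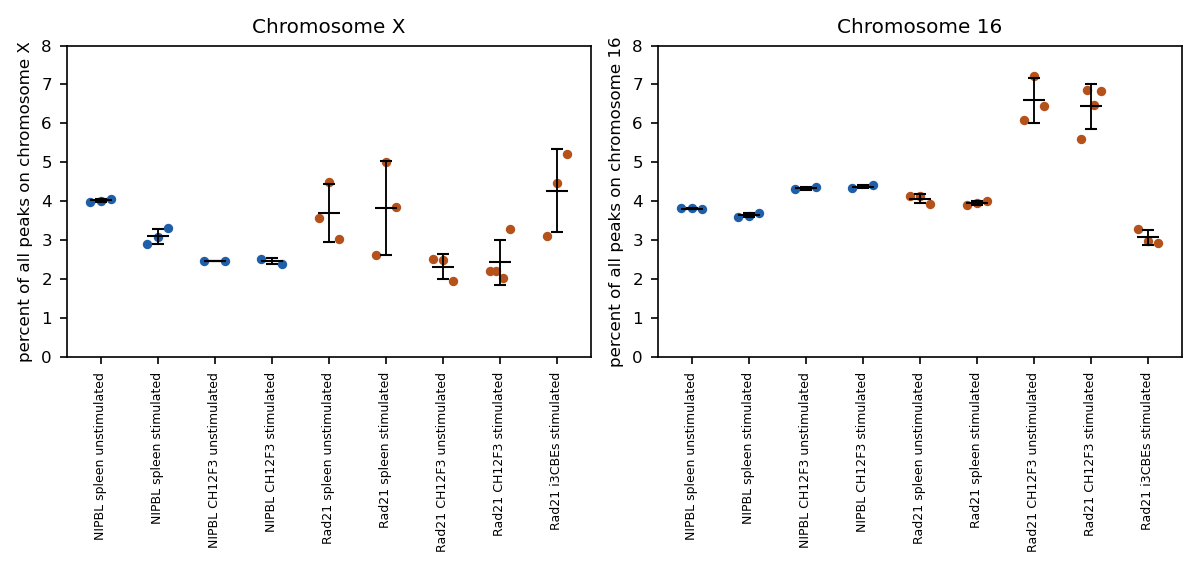
Percent of all deposited peaks on the X chromosome and on chromosome 16 (vertical axes, 0 to 8) in the 9 groups; points are libraries (NIPBL blue, Rad21 orange), horizontal lines are means and bars are 1 SD. The share on X is 3.10% in stimulated and 4.02% in unstimulated splenic NIPBL libraries, and the share on chromosome 16 is 3.08% in i3CBEs and 6.44% in stimulated CH12F3.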

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

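The tests on a control shared by both antibodies, on the sex of the donors and on the other divisions of the libraries into groups were chosen only after the result was seen, as were the 3 patterns weighed; the other tests below were written down before their values were known. Samples far from the others were looked for in groups of 4 or more libraries, which stimulated CH12F3 Rad21 alone has. Of 15 sets of values tested, 6 had such a sample, where chance gives about 1 in 20 for values that vary freely; in 2 of the 6, all other libraries are at 0, so any covered library stands apart by construction. Replicate 4 had the highest share of peaks on the X chromosome, 3.292% (nearest other 2.214%), and on the Y chromosome, 0.00374% (nearest other 0.001048%). In the IgH region it covered the least of 12:114310001, 2.83% (nearest other 4.43%), and was alone in covering 12:114660001, at 0.51%. Replicate 3 covered the least of 12:114380001, 2.61% (nearest other 3.62%), and replicate 2 was alone in covering 12:114500001, at 2.98%. A difference between groups was tested by interaction: limma called a different effect of stimulation in spleen and CH12F3 in 3 bins for NIPBL and 1277 for Rad21, but in 514 and 353 with 10000 top peaks, in 0 and 1 with all deposited peaks (20598 and 4158 with an unadjusted p under 0.05), in 3394 for NIPBL without NIPBL CH12F3 unstimulated replicate 2 and in 490 for Rad21 with the replicate block and without CH12F3 stimulated replicate 4. Among data not used in the comparisons, i3CBEs lists held 753, 700 and 604 peaks on sequences outside the main chromosomes, where the other lists held 1 to 18.

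Chromosome 16 held 3.08 ± 0.190% of Rad21 peaks in i3CBEs (n = 3) and 6.44 ± 0.585% in stimulated CH12F3 (n = 4). Shorter lists alone do not account for this, since in lists of equal length the share still differed by -0.742 percentage points (3.25 ± 0.0765% against 3.99 ± 0.0869%) without overlap. Of 10 windows of 10 Mb along the chromosome, 8, or 80%, were lower without overlap for all deposited peaks, with ratios from 0.396 to 0.649. A different copy number of chromosome 16 in the 2 lines may account for the lower share. These lists differ in length, however, and windows were not counted in lists of equal length. Splenic Rad21 lists held 3.91 to 4.15% on chromosome 16, between the 2 lines and nearer to i3CBEs. NIPBL lists held 4.31 to 4.41% in CH12F3 and 3.61 to 3.83% in spleen. The pattern may thus be a raised share in CH12F3 as well as a lower one in i3CBEs. Different control and reference sequences cannot be told apart from the line, as 0 CH12F3 libraries were called against the i3CBEs control. A difference in cohesin binding between i3CBEs and CH12F3 is the biological explanation the design offers, and it was not tested apart from these.

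Splenic NIPBL lists held 3.10 ± 0.200% of their peaks on the X chromosome after stimulation and 4.02 ± 0.0373% before it (n = 3 each). A difference in list length alone does not account for this, because lists of 20000 peaks differed by -1.15 percentage points (1.87 ± 0.123% against 3.02 ± 0.49%) without overlap. All 17 windows of 10 Mb, or 100%, were lower without overlap for all deposited peaks, with ratios from 0.613 to 0.906, so a different dosage of the whole chromosome could account for it. Windows were not counted in lists of equal length. Most other chromosomes also had shares of all peaks without overlap between the states, so a lack of overlap does not single out X. Donors of another sex cannot be told apart: the Y share before over that after stimulation was 0.901 for all peaks, where a mix of sexes with this X ratio allows at most 0.703, but for the 20000 top peaks it was 0.558 (0.375 at the lowest between libraries) with at most 0.388 allowed, and the labels give no sex. An effect of stimulation on the X chromosome stays open, since each state has its own libraries.

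Rad21 and NIPBL were both lower in 28 bins of stimulated splenic B cells, where 7.96 were expected. Uneven list length was tested by comparing long Rad21 lists among themselves (2 stimulated, 1 unstimulated) and short ones among themselves (1 and 2). Rad21 was lower in 73.4% of the bins that lost NIPBL for long lists (58.9% of all tested bins) and in 95.3% for short lists (80.8%), but each class has an arm of 1 library and most tested bins were lower in both, so this test decides nothing and list length cannot be told apart from a joint loss. With a term for list length limma called 0 bins for Rad21 (1022 higher and 2750 lower had an unadjusted p under 0.05). A control shared by both antibodies cannot be told apart either, because 0 NIPBL lists of spleen name a control. A joint loss of loader and cohesin is an untested hypothesis.

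Other divisions of the same libraries into groups of the same sizes were counted. For i3CBEs against stimulated CH12F3, 1 of 35 divisions, the real one, called as many bins (94; highest other 88, with CH12F3 replicate 4 beside i3CBEs). That share is under 0.05 only before correction for the 4 comparisons, and without CH12F3 replicate 1 no more than 3 higher and 3 lower bins were called, so chance is not firmly excluded. For Rad21 in CH12F3, 8 of 35 called 6 or more, so chance is not excluded. The highest other called 599 bins and set stimulated and unstimulated replicates 1 and 3 apart from the rest, which points to a structure of the samples. For NIPBL in spleen (548 bins; highest other 1) and Rad21 in spleen (637; highest other 0), 1 of 10 divisions called as many, and 10 are too few for a share under 0.05.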

How the results depend on the processing

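Bins of 5 kb, bins scored as covered or not, the term for list length and the fit without X and Y were chosen only after the result was seen. The rule for named bins, with the called IgH bins, picked 84 bins, not all of which the text names. They had 1308 values under alternatives: 696 kept their sign and their side of the threshold, 565 kept their sign and lost the call, 12 kept their sign and gained it and 35 reversed. In 60 bins no alternative reversed the sign. Where values below changed, the cause was not tested. Read depth is unknown, so lists of equal length stand in for equal depth and limit what weak peaks can show. A lone library left in a group was assumed to vary like the other group. Alternatives planned for promoters, gene lists and motifs were not run, for lack of an mm9 annotation. With 2 pairs, the correlation for NIPBL in CH12F3 (r of 0.313) cannot show pairing. Same numbers showed no pairing for NIPBL in spleen (r from -0.0992 to -0.0176) Rad21 in spleen (-0.119 to 0.0267) or i3CBEs (-0.0741 to 0.103).

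Counts are higher and lower bins, in that order. With 10000 top peaks: NIPBL in spleen 380 and 458, Rad21 in spleen 0 and 0, Rad21 in CH12F3 1 and 3, interaction 514 for NIPBL and 353 for Rad21; IgH bins without overlap 3 for NIPBL in spleen, 1 for Rad21 in spleen, 0 for Rad21 in CH12F3 and 1 for i3CBEs; differences reversed at Y:2790001 (-1.31), 4:133680001 (-1.61) and 1:87500001 (6.26). With 40000: NIPBL in spleen 331 and 66, Rad21 in spleen 0 and 0, Rad21 in CH12F3 lower 13, i3CBEs lower 35; reversed at 18:35020001 (-21.9), 11:3070001 (-1.54), 1:80750001 (-2.84), 16:97010001 (-0.626), 8:87100001 (-1.41), 13:42880001 (-0.889) and 9:77600001 (0.134). With equal covered length: NIPBL in spleen 517 and 454, Rad21 in spleen 0 and 0, Rad21 in CH12F3 lower 0, i3CBEs 1694 and 200; reversed at 18:35020001 (-4.74). With all deposited peaks: NIPBL in spleen 1442 and 89, Rad21 in spleen 0 and 6, Rad21 in CH12F3 lower 0, i3CBEs 0 and 56, interaction 0 for NIPBL and 1 for Rad21. IgH bins without overlap were then 17 and 6 for NIPBL in spleen and CH12F3, and 3, 0 and 7 for Rad21 in spleen, CH12F3 and i3CBEs. Differences reversed at 12:114400001 (12.1), 16:80610001 (-0.295), 3:31360001 (-6.14), 3:53170001 (-3.39), 18:35020001 (-4.205), 9:77390001 (0.885), 16:37860001 (0.99), 11:3070001 (-1.54), 1:80750001 (-2.95), 16:97010001 (-0.541), 13:22810001 (-0.0742), 13:42880001 (-0.597), 6:47690001 (-9.74) and 12:86870001 (-6.88).

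Peaks with a -log10 q of 5 or more gave NIPBL in spleen 0 and 0, Rad21 in spleen 0 and 0, Rad21 in CH12F3 lower 0, i3CBEs 11 and 406; reversed at 15:75930001 (-4.39), 12:114470001 (-2.79), 11:35240001 (-0.205), 16:80610001 (-0.655), 18:35020001 (-15.035), 15:81410001 (0.15), 11:3070001 (-1.57), 1:80750001 (-1.25), 6:47690001 (-6.54) and 17:13740001 (-0.5775). Ranking by fold enrichment gave Rad21 in spleen higher 19. Bins of 5 kb gave Rad21 in CH12F3 1 and 11, i3CBEs 67 and 106. Scoring by 50% covered, which left few bins, gave NIPBL in spleen 3 and 2, NIPBL in CH12F3 lower 2, Rad21 in spleen 1 and 3, Rad21 in CH12F3 lower 0, i3CBEs 0 and 8. Scoring as covered or not gave NIPBL in CH12F3 860 and 1429, Rad21 in spleen 909 and 1255, Rad21 in CH12F3 12 and 14, i3CBEs 95 and 124. The counts for NIPBL in CH12F3 have the limit given with that comparison. Without a filter: Rad21 in spleen 0 and 0, Rad21 in CH12F3 higher 1, i3CBEs higher 66. Array weights gave Rad21 in spleen 1040 and 2896, Rad21 in CH12F3 lower 2, i3CBEs 72 and 474, interaction for Rad21 2439. All groups in 1 fit gave NIPBL in spleen 174 and 126, NIPBL in CH12F3 70 and 186, Rad21 in spleen 1122 and 2738, Rad21 in CH12F3 4 and 10, i3CBEs higher 69. The replicate block, which for CH12F3 Rad21 also leaves out stimulated replicate 4 (without it alone: Rad21 in CH12F3 1 and 3, i3CBEs 69 and 211, interaction 1028), gave NIPBL in spleen 0 and 0, NIPBL in CH12F3 0 and 0 (492 and 654 with an unadjusted p under 0.05), Rad21 in CH12F3 lower 0, i3CBEs 5 and 2, and interaction 0 for NIPBL (2410 with an unadjusted p under 0.05) and 490 for Rad21; for Rad21 in spleen the counts stayed within 1.5 times. The list length term gave Rad21 in spleen 0 and 0. Under settings where limma called 0 bins in both directions, bins with an unadjusted p under 0.05 numbered 1621 to 13542 for NIPBL in spleen, 38 to 7119 for NIPBL in CH12F3, 2143 to 5369 for Rad21 in spleen and 1 to 4720 for Rad21 in CH12F3.

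With each replicate left out, NIPBL in spleen had 217 (without unstimulated 2) to 655 (without unstimulated 1) higher bins and 199 (without stimulated 2) to 371 (without unstimulated 3) lower. NIPBL in CH12F3 had 0 to 0. Rad21 in spleen had 0 to 47 higher and 0 (without any stimulated replicate) to 1759 (without unstimulated 3) lower. Rad21 in CH12F3 had 0 to 18 higher (18 without unstimulated 2) and 0 (without unstimulated 3 or stimulated 3) to 177 (without unstimulated 2) lower. i3CBEs had 3 (without CH12F3 1) to 72 (without i3CBEs 1) higher and 2 (without i3CBEs 2) to 211 (without CH12F3 4) lower. Interaction counts were 2 to 3394 for NIPBL and 909 to 2485 for Rad21 (highest without NIPBL CH12F3 unstimulated replicate 2 and Rad21 spleen unstimulated replicate 3). IgH bins without overlap were 10 to 12 and 4 to 10 for NIPBL in spleen and CH12F3, and 0 to 3, 2 to 3 and 2 to 6 for Rad21 in spleen, CH12F3 and i3CBEs. Overlap of 50% of the peak gave Rad21 64.5% within and 58.7% between groups in spleen, 81.5% and 82.7% in CH12F3, 73.0% for i3CBEs and CH12F3, 59.7% for spleen and CH12F3, and 6.90% with NIPBL in spleen. With all peaks these were 26.2%, 24.6%, 43.7%, 45.1%, 46.3%, 30.3% and 14.8%, with 20.7% for NIPBL and Rad21 in CH12F3, and NIPBL gave 25.7% and 25.0% in spleen and 29.8% within CH12F3.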

Other observations

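Every choice of bins here was made after the data were seen, and no test was run on them apart from the regroupings. Rad21 covered 8760 bins in all 16 libraries, of 40239 covered in any. A further 302 bins were covered in all 6 splenic libraries and in no CH12F3 or i3CBEs library, and 557 in all 10 CH12F3 and i3CBEs libraries and in no splenic one. In 100 random regroupings of the 16 libraries the highest counts were 10 and 2. Among the spleen bins were 4:97410001, covered at 14.6 ± 6.29% (SD, n = 6), 13:117980001 at 15.2 ± 5.43% and 2:173270001 at 13.5 ± 7.31%. Among the CH12F3 and i3CBEs bins were 1:85340001 at 24.3 ± 13.1% (n = 10), 4:73260001 at 8.26 ± 2.26% and 15:57370001 at 9.06 ± 2.67%. NIPBL covered 2065 bins in all 10 of its libraries and 7187 in all 6 from spleen. Of the splenic bins, 336 had no NIPBL peak in any CH12F3 library, whereas 26 were covered in the 4 CH12F3 libraries and in no splenic one. Both antibodies together covered 347 bins in all 26 libraries.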
